A study of Mus musculus with 12 samples.

How the data were processed

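RNA was measured by 3′ mRNA sequencing in 12 libraries of a mouse B cell lymphoma line, in 6 groups of 2: RPL12 WT, S38A or S38D, each asynchronous or mitotic. Per the labels, mitotic cells received 100 ng/mL nocodazole for 8 h and were released for 10 min, and all cells were harvested in cycloheximide at 100 µg/mL. Total RNA was taken from cleared polysome lysates, and 1 µg with ERCC spike-in RNA entered a QuantSeq 3′ forward library, sequenced to 51 nt with 12 libraries per lane. The deposited files hold counts, 1 per library: whole numbers of reads for 51826 genes and 92 spike-ins, without normalization. The authors name bcl2fastq 2.16.0.10, cutadapt 1.12, STAR 2.5.3a and the genome build mm10. The program that counted reads, its strand setting, its treatment of reads with several matches and the gene annotation are not given in the sources used here. Gene reads per library ranged from 3432875 to 6587997 with a median of 5548100. Counting intervals and floors (3 reads) cover counting error only, since reads of amplified libraries are not independent molecules.

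Gene symbols and positions were taken from GENCODE M21 on GRCm38, which matched 51633 gene identifiers (99.63%). Genes were filtered with filterByExpr by group at a minimum count of 10, which left 10477. Libraries were scaled with TMM factors and fitted in edgeR 4.0.16 (R 4.3.3) with a mean per group and no other term, with 6 residual degrees of freedom, a median prior of 9.95 degrees and a common biological coefficient of variation of 0.143. Quasi-likelihood F tests with robust estimation were adjusted by Benjamini-Hochberg over all genes tested within each of 13 comparisons, and genes with an adjusted p under 0.05 were called. The comparisons were mitotic against asynchronous cells (over the 3 lines and in each), S38A and S38D against WT and S38D against S38A in each state, and the differences between lines in the mitotic change. Log2 fold changes are fitted values with an SE derived from the F statistic. CPM are TMM-scaled means with the SD between libraries.

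Before the data were examined, 31 gene lists were written down, together with the comparisons, the tests, the rule for named genes and the first set of alternatives. They cover G2/M, G1/S, tubulin, replication-dependent histone, cytosolic ribosomal protein, ribosome biogenesis, translation factor, immediate early, ATF4, p53, ER unfolded protein response, heat shock, mitochondrially encoded, OXPHOS, nuclear long noncoding, detained-intron, B cell identity, germinal centre, plasma cell, immunoglobulin constant region, MHC class II, interferon, NF-kB, cholesterol, glycolysis, FOXO, apoptosis and proteasome genes. Markers of T and NK cells, of myeloid cells, and of stromal, epithelial and erythroid cells complete them. The 30 lists with at least 3 measured members were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were run beside it.

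Named genes followed a rule in parts. Rpl12 is given in every comparison. Called genes with a mean of at least 10 CPM, libraries of the groups apart and a symbol other than a predicted or clone name were ranked by fold change. The first 10 in each direction were named for the mean mitotic comparison, 6 for each mutant line against WT, and 4 for S38D against S38A and for the differences in the mitotic change, where separation was not required. For each list, the 3 members with the smallest adjusted p were eligible. The last part named 5 genes called in the same direction in all 4 comparisons of a mutant line with WT. The text and plots leave out 3 of the genes that the rule selects, which still count in the totals and lists. Chromosome 12, the windows of neighbouring genes and the class of small nuclear and nucleolar RNAs fall outside this rule and were chosen after their values were seen.

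The alternatives fixed in advance were DESeq2 1.42.0, limma-voom, DESeq2 size factors within edgeR, scaling to the spike-in total, no filter, a 10 CPM filter, robust estimation off, only the groups compared, the replicate number as a block and each library left out in turn. A fit with 1 library left out leaves a lone library in its group, which is assumed to vary like the other groups. Replicate numbers did not pair the samples consistently. Of the 15 correlations of replicate differences between groups, across 5971 genes, 3 were above 0.1 and 3 below -0.1. The high ones joined S38D asynchronous with WT mitotic (0.811) and S38A mitotic (0.627), and the latter pair with each other (0.586). The low ones set S38A asynchronous against these same groups (-0.448 to -0.402). Alternatives added after seeing the data were the position of each library on the first axis of within-group deviations as a covariate, offsets for GC content over the last 300 nt of the transcript, and both libraries far from their replicates left out. No library was left out of the reported values.

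The pipeline was tested on simulated data with planted changes. For S38A against WT in mitotic cells it recovered 51% of 100 genes planted at 2-fold and 86% of 100 at 4-fold, with 11 false among 148 calls. For the mean mitotic comparison it recovered 82% and 98%, with 11 false calls, and for a difference in the mitotic change 20% and 63%, with 7 false calls. All 3 planted lists and 0 of 27 others were called by camera. Genes varied independently in these simulations, without the axis of within-group deviations. The recovered shares and false calls hold for such data and may differ in the real libraries. Nor does the list result show how often camera calls a list falsely where genes vary together, as in the real libraries.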

Results

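RNA abundance was measured by 3′ mRNA sequencing in 12 libraries from 19DN, a reporter-negative subline of the mouse B cell lymphoma line 19PP, which was driven by Myc and an active PI3K subunit. The cells carried wild-type RPL12 (WT), a protein of the large ribosomal subunit near the site where translation factors bind, or RPL12 with serine 38 replaced by alanine (S38A) or by aspartate (S38D). Each line was collected as asynchronous culture and as mitotic cells, arrested with nocodazole, a drug that takes microtubules apart, at 100 ng/mL for 8 h and released for 10 min. Each of the 6 groups of line and state had 2 libraries. Reads assigned to genes numbered 4908697 and 3432875 in the WT asynchronous libraries, 6587997 and 6046872 in S38A, and 6523991 and 5660515 in S38D. In the mitotic libraries they numbered 5301264 and 4428618 for WT, 5603135 and 5594973 for S38A, and 4835504 and 5501227 for S38D. Between 13378 and 14331 genes had at least 1 read in a library.

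Replicates differed by more than counting error in every group. The share of genes outside the 95% range of counting error was 16.1% in WT asynchronous, 22.1% in S38A asynchronous, 50.8% in S38D asynchronous, 31.6% in WT mitotic, 24.4% in S38A mitotic and 18.7% in S38D mitotic. One axis of genes held 73.2% of the variance within groups, with S38D asynchronous replicate 1 at -30.4 and replicate 2 at 12.8, and WT mitotic replicate 1 at -21.7 and replicate 2 at 5.04. Each p-value below therefore measures only the spread between these samples, which may be technical. ERCC spike-in RNA, added at a fixed amount to the same mass of total RNA, made up 2.5% ± 0.293 of gene reads in WT asynchronous (SD, n = 2) and means of 3.09% to 3.4% in the other 5 groups. Fold changes are relative to the bulk of the genes, and scaling to the spike-ins instead shifted the median of all genes by -0.18 (log2) in the mean mitotic comparison, -0.44 in WT and -0.11 in S38D. The same scaling shifted it by -0.45 for S38A against WT and -0.38 for S38D against WT in asynchronous cells, and by 0.46, 0.33 and -0.13 in the differences of the mitotic change (S38A against WT, S38D against WT and S38D against S38A).

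The first comparison asked how the RNA of mitotic cells differed from that of asynchronous cells, over the 3 lines. Only the mitotic cells had received nocodazole and the release, so cell state and treatment were not separated. Immediate early genes, which respond to growth and stress signals within minutes, rose in 24 of 36 cases and fell in 3, and Fos rose most, from 0.499 ± 0.189 to 46.3 ± 16.5 CPM (read counts scaled to library size; SD, n = 6 libraries per state). Tubulin genes, which encode the building blocks of microtubules, fell in 7 of 9 cases, with Tubb5 at 554 ± 112 CPM in mitotic and 2173 ± 542 CPM in asynchronous libraries. B cell identity genes fell in 29 of 37 cases and germinal centre genes in 17 of 24, among them Nuggc, a nuclear GTPase of germinal centre B cells, from 100.0 ± 25.8 to 33.2 ± 18.1 CPM. Of 68 ribosome biogenesis genes 46 rose and 2 fell, and of 18 replication-dependent histone genes 7 rose and 1 fell. With an estimated correlation these list calls had an adjusted p = 0.0656 and an adjusted p = 0.0781. Of 10477 genes tested, 4407 were called by edgeR quasi-likelihood tests with Benjamini-Hochberg adjustment, 2145 higher and 2262 lower in mitotic libraries, and 637 of them changed at least 2-fold. Scaled to the spike-ins, 1035 were higher and 3344 lower.

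Of 36 immediate early genes measured, 24 rose and 3 fell (25 and 3 adjusted over the list alone), with a median log2 fold change of 0.83 (camera adjusted p = 4.02e-19). Fos (chromosome 12, 85473890 to 85477273, GRCm38) rose by 6.44 on the log2 scale (SE 0.207, adjusted p = 2.72e-12). Its partner Jun (chromosome 4, 95049034 to 95052222) rose by 3.22 (SE 0.121, adjusted p = 1.39e-11). Fosb (chromosome 7, 19302696 to 19310051) rose by 3.55 (SE 0.0997, adjusted p = 6.52e-13). Egr1, a zinc finger transcription factor, rose by 2.11 (SE 0.147, adjusted p = 6.47e-06) and Rgs2, a regulator of G protein signalling, by 3.01 (SE 0.0753, adjusted p = 2.15e-13). Id2, an inhibitor of basic helix-loop-helix transcription factors, rose by 2.22 (SE 0.146) and Tent5c, a poly(A) polymerase active in plasma cells, by 2.33 (SE 0.0788). The small nucleolar RNA Snora30 rose by 5.20 (SE 0.19, adjusted p = 9.81e-12), with 864 mitotic against 21 asynchronous reads. Scarna9 rose by 3.16 (SE 0.141) and Snora73b by 2.60 (SE 0.17). Each of these genes was higher in all 6 mitotic libraries than in any asynchronous library. Whether reads of 3′ mRNA libraries follow the amount of the small RNAs was not tested.

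Of 9 tubulin genes, 7 fell and none rose (8 and 0 adjusted over the list alone), with a median of -1.30 (camera adjusted p = 4.02e-19). Tubb5 (chromosome 17, 35833921 to 35838306) changed by -1.96 (SE 0.0797, adjusted p = 4.28e-11), Tubb2a by -1.86 (SE 0.108) and Tuba1a by -1.46 (SE 0.0616). B cell identity genes included 29 of 37 that fell and none that rose (30 and 0 adjusted over the list alone), with a median of -0.60 (camera adjusted p = 2.67e-19). Vpreb3, a B lineage gene, changed by -2.34 (SE 0.118), the transcription factor Spib by -1.07 (SE 0.0629) and the coactivator Pou2af1 by -1.25 (SE 0.073). Of 24 germinal centre genes 17 fell and 2 rose (the same counts adjusted over the list alone), with a median of -0.84 (camera adjusted p = 8.08e-16). The lipid receptor gene S1pr2 changed by -1.32 (SE 0.0598, adjusted p = 1.43e-10) and Nuggc by -1.72 (SE 0.0884, adjusted p = 6.77e-10). Bach2, a repressor that restrains plasma cell differentiation, changed by -2.33 (SE 0.146), Wfdc21 by -2.06 (SE 0.113), Nxpe2 by -1.82 (SE 0.167) and Plek by -1.72 (SE 0.118).

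Of 24 genes of MHC class II and antigen presentation, 13 fell and 3 rose (14 and 3 adjusted over the list alone), with H2-Aa at -1.72 (SE 0.0575) and H2-DMb2 at -0.77 (SE 0.0662). The list's call (camera adjusted p = 0.0002) had an adjusted p = 0.0609 with an estimated correlation. G2/M genes were lower too, with 33 of 66 down and 1 up (34 and 1 adjusted over the list alone, median -0.39, camera adjusted p = 2.52e-08). Cdc25b, a phosphatase of mitotic entry, changed by -1.31 (SE 0.0706) and Nusap1, a spindle protein, by -1.46 (SE 0.0813). This list was fixed as genes whose mRNA is highest in G2 and mitosis of cycling cells. The mitotic state was taken from the labels, and the direction of this list gives no support for it. Of 65 G1/S and replication genes, 32 fell and 3 rose (37 and 3 adjusted over the list alone; median -0.29, camera adjusted p = 1.3e-05), with Clspn, a replication checkpoint adaptor, at -0.94 (SE 0.0734). ATF4 targets, the genes of the integrated stress response, fell in 23 of 39 cases and rose in 5 (26 and 5 adjusted over the list alone; median -0.37, camera adjusted p = 2.4e-05). The call had an adjusted p = 0.14 with an estimated correlation. Ddit4, an mTORC1 inhibitor, changed by -1.04 (SE 0.0594) and Trib3, a pseudokinase, by -0.95 (SE 0.0755).

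Of 68 ribosome biogenesis genes, 46 rose and 2 fell (46 and 3 adjusted over the list alone; median 0.40, camera adjusted p = 1.28e-09), with Rrp9 at 0.93 (SE 0.0751) and Rrp1b at 0.67 (SE 0.057). Of 18 replication-dependent histone genes, whose main transcripts lack a poly(A) tail, 7 rose and 1 fell (the same adjusted over the list alone; median 0.60, camera adjusted p = 1.36e-05), with Hist1h4i at 1.89 (SE 0.0597). These calls had an adjusted p = 0.0656 and an adjusted p = 0.0781 with an estimated correlation. Of 7 mRNAs encoded in the mitochondria, 3 rose (the same adjusted over the list alone; median 0.40, camera adjusted p = 0.0132; adjusted p = 0.279 with an estimated correlation), with mt-Co1 at 0.55 (SE 0.0655). Of 79 cytosolic ribosomal protein genes, 22 rose and 8 fell (the same adjusted over the list alone), with a median of 0.09 that became -0.08 under spike-in scaling. That list's call (camera adjusted p = 0.0405) had an adjusted p = 0.515 with an estimated correlation and an adjusted p = 0.144 under spike-in scaling. Rpl12 itself (chromosome 2, 32961559 to 32965345) rose by 0.61 (SE 0.0929, adjusted p = 7.12e-05), from 38.2 ± 5.64 to 58.8 ± 13.3 CPM. These reads lie at the 3′ end, do not show codon 38, and may be shared with pseudogenes, since how reads with several matches were counted is not stated.

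**Figure D1:**
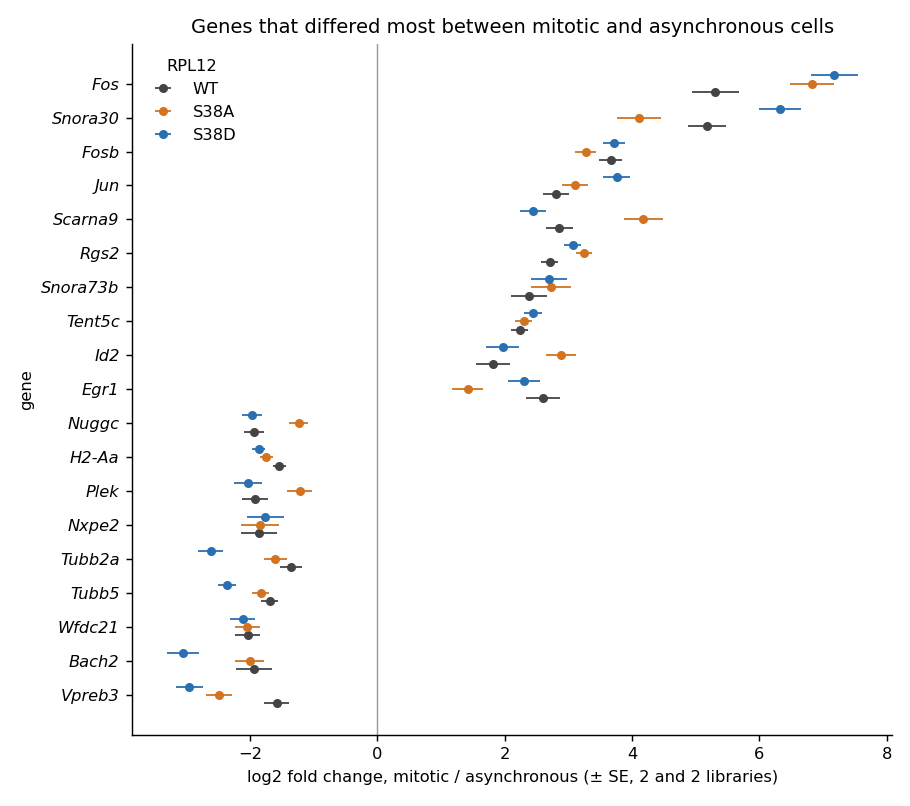
Log2 fold change (± SE) of 19 of the 20 genes that the rule selects for the mean mitotic comparison, mitotic against asynchronous, drawn for WT, S38A and S38D (2 and 2 libraries each). Fos stood at 5.31, 6.83 and 7.18, and Tubb5 at -1.69, -1.83 and -2.36.

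**Figure D2:**
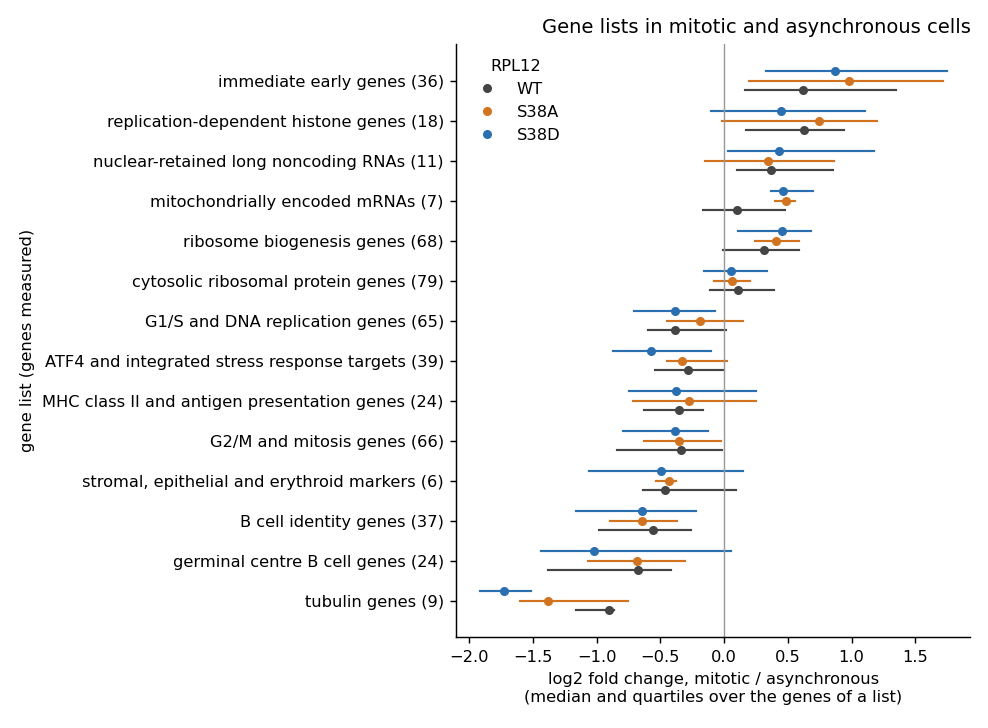
Median (dots) and quartiles (lines) of the log2 fold change, mitotic against asynchronous, over the genes of each of the 14 lists called in the mean comparison, drawn for WT, S38A and S38D, with tubulin genes at -0.90, -1.38 and -1.72. Under spike-in scaling the WT medians of ribosome biogenesis genes (0.31), mitochondrially encoded mRNAs (0.10), nuclear-retained long noncoding RNAs (0.37) and cytosolic ribosomal protein genes (0.11), and the S38D median of the last (0.06), turned negative.

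Within single lines, Fos rose by 5.31 in WT (SE 0.367), 6.83 in S38A (SE 0.343) and 7.18 in S38D (SE 0.367), and Tubb5 changed by -1.69 (SE 0.137), -1.83 (SE 0.137) and -2.36 (SE 0.14). Of 25 cholesterol biosynthesis genes in WT, 12 rose and 3 fell (14 and 3 adjusted over the list alone; median 0.36, camera adjusted p = 0.00262), with Dhcr7, an enzyme of the last steps, at 1.09 (SE 0.149), a median that turned to -0.09 under spike-in scaling. The WT call had an adjusted p = 0.101 with an estimated correlation. In S38A 12 of these genes fell and none rose (15 and 0 adjusted over the list alone; median -0.44, camera adjusted p = 8.47e-08), with Nsdhl at -0.86 (SE 0.107). In S38D 8 fell and 2 rose (the same adjusted over the list alone; median -0.21, camera adjusted p = 0.01; adjusted p = 0.0945 with an estimated correlation), with Hmgcs1, which feeds the pathway, at -0.81 (SE 0.104). Rpl12 rose by 0.90 in WT (SE 0.162, adjusted p = 0.00092) and 0.78 in S38D (SE 0.162, adjusted p = 0.00208; 0.0543 without S38D mitotic replicate 2), against 0.14 in S38A (SE 0.159, adjusted p = 0.623).

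The edgeR test called 2727 genes in WT (1399 higher, 1328 lower), 1548 in S38A (704 and 844) and 2762 in S38D (1211 and 1551), with 392 genes higher and 405 lower in all 3 lines and 32 called opposite ways in any pair of lines. Under spike-in scaling the higher and lower counts were 217 and 3232 in WT and 603 and 1618 in S38D. The WT count was 1121 and 1567 without WT asynchronous replicates 1 and 2 and 1302 without WT mitotic replicate 1. The S38A count was 630 and 725 without S38A asynchronous replicates 1 and 2, 713 and 658 without S38A mitotic replicates 1 and 2, and 2446 and 2421 without S38D asynchronous replicates 1 and 2. The S38D count was 1690 and 1462 without S38D mitotic replicates 1 and 2.

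The next comparisons asked which genes differed between each mutant line and WT in asynchronous cells. In S38A, Ptprcap, which encodes a partner of the phosphatase CD45, was nearly absent, with 0.244 ± 0.101 CPM (SD, n = 2; 3 reads) against 33.7 ± 4.01 CPM in WT. Wnt10a, a secreted Wnt ligand, Car2, a carbonic anhydrase, and Kcnab2, a potassium channel subunit, fell, while Ackr4, a scavenging chemokine receptor, and Slc41a2, a magnesium transporter, rose. In S38D, Ptprcap, the C-type lectin Clec4d and Lat2, an adaptor of B cell receptor signalling, fell, and the linker histone H1f0 rose. Of 39 ATF4 targets, 16 fell and 2 rose in S38A (adjusted p = 0.0566 for the list with an estimated correlation). In S38D 17 fell and none rose. The edgeR test called 2223 genes in S38A (1224 higher, 999 lower, 720 at least 2-fold) and 942 in S38D (510 higher, 432 lower, 322 at least 2-fold). Scaled to the spike-ins, 3115 of 3317 called genes were lower in S38A and 1307 of 1365 in S38D.

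In asynchronous S38A cells Ptprcap (chromosome 19, 4153604 to 4156751) changed by -6.97 (SE 0.445, adjusted p = 5.46e-08), with a counting interval of -9.51 to -5.66 for its 3 reads against 296. Wnt10a changed by -5.20 (SE 0.278, adjusted p = 1.01e-08), Clec4d by -4.61 (SE 0.324) and Car2 by -4.24 (SE 0.522). The fetal serum protein gene Afp changed by -4.11 (SE 0.286), Kcnab2 by -4.02 (SE 0.232) and Map1a, a microtubule-associated protein gene, by -3.31 (SE 0.246). Ackr4 (chromosome 9, 104084157 to 104126933) rose by 2.66 (SE 0.178, adjusted p = 6.83e-08), Shisa8 by 2.39 (SE 0.158) and Fam167b by 2.36 (SE 0.262). Plxnb2, a semaphorin receptor, rose by 2.15 (SE 0.159), Slc41a2 by 2.12 (SE 0.134) and the translation initiation factor Eif5b by 2.21 (SE 0.196). Lat2 changed by -1.86 (SE 0.165). Rpl12 differed by 0.12 (SE 0.163, adjusted p = 0.629), with 43.0 ± 2.39 CPM in S38A and 39.5 ± 0.551 CPM in WT.

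In asynchronous S38D cells Ptprcap changed by -5.44 (SE 0.376, adjusted p = 2.81e-07), Clec4d by -3.80 (SE 0.298), Map1a by -2.57 (SE 0.232), Lat2 by -2.67 (SE 0.174), Afp by -2.83 (SE 0.254) and Cth, which makes cysteine from cystathionine, by -2.61 (SE 0.371; adjusted p = 0.167 with only the groups compared). H1f0 rose by 2.45 (SE 0.304, adjusted p = 0.000313), Tmem121 (chromosome 12, 113185930 to 113189523) by 2.04 (SE 0.187) and Plxnb2 by 1.90 (SE 0.159). Fcho1, an endocytosis gene, rose by 1.82 (SE 0.202), Tmem101 by 1.66 (SE 0.203) and Fam167b by 1.66 (SE 0.268). Cystm1 changed by -3.34 (SE 0.644, adjusted p = 0.0267), with adjusted p = 0.135 and 0.102 without WT asynchronous replicates 1 and 2, and from 0.0511 to 0.0567 without either S38A replicate of either state. Fam167b had an adjusted p = 0.0505 without WT asynchronous replicate 1. With only the groups compared, Cystm1 had an adjusted p = 0.28 and Fam167b an adjusted p = 0.0703. Rpl12 differed by -0.30 (SE 0.165, adjusted p = 0.275), which became -0.69 with an adjusted p = 0.0168 under spike-in scaling.

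Among ATF4 targets in asynchronous cells, 16 of 39 fell and 2 rose in S38A (20 and 2 adjusted over the list alone; median -0.38, camera adjusted p = 4.48e-10; adjusted p = 0.0566 with an estimated correlation). In S38D 17 fell and none rose (22 and 0 adjusted over the list alone; median -0.63, camera adjusted p = 6.45e-23). Trib3 changed by -1.58 in S38A (SE 0.128) and -1.91 in S38D (SE 0.13), Ddit3, a stress transcription factor gene, by -1.28 (SE 0.13) and -1.49 (SE 0.131), and Cebpb by -2.28 (SE 0.18) and -1.90 (SE 0.177). B cell identity genes rose in 23 of 37 cases and fell in 1 in S38A (25 and 1 adjusted over the list alone; camera adjusted p = 1.34e-08), with a median of 0.42 that became -0.04 under spike-in scaling. In S38D 15 rose and 1 fell (20 and 3 adjusted over the list alone; camera adjusted p = 3.34e-08), with a median of 0.38 that became -0.01 under that scaling. Cr2, the complement receptor CD21, stood at 1.54 (SE 0.143) and 1.29 (SE 0.143). Of 66 G2/M genes 31 rose and 1 fell in S38A (34 and 2 adjusted over the list alone; camera adjusted p = 2.21e-06), with a median of 0.38 that became -0.06 under spike-in scaling and the centromere protein gene Incenp at 1.61 (SE 0.169). Of 65 G1/S genes 25 rose and none fell in S38A (26 and 0 adjusted over the list alone; camera adjusted p = 1.17e-06). In S38D 16 rose and none fell (28 and 0 adjusted over the list alone; camera adjusted p = 1.9e-06). Their medians of 0.29 and 0.27 became -0.16 and -0.08 under spike-in scaling. FOXO targets, which PI3K signalling represses, fell in 6 of 21 cases in S38D (the same adjusted over the list alone; median -0.47, camera adjusted p = 0.000691), with Cdkn1b, a cyclin-dependent kinase inhibitor, at -2.62 (SE 0.344).

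Markers of stromal, epithelial and erythroid cells also moved with line and state. In asynchronous S38A cells 4 of 6 measured rose (the same adjusted over the list alone; median 0.81, camera adjusted p = 0.000715; adjusted p = 0.0566 with an estimated correlation), with the intermediate filament gene Vim at 1.00 (SE 0.15) and the beta globin gene Hbb-bt at 0.63 (SE 0.108; 0.18 with an adjusted p = 0.335 under spike-in scaling). In mitotic S38A cells 3 of 6 rose (the same adjusted over the list alone; median 0.46, camera adjusted p = 0.00112), and in mitotic cells of the 3 lines 3 of 6 fell (the same adjusted over the list alone; median -0.44, camera adjusted p = 0.013; adjusted p = 0.0781 with an estimated correlation). Hbb-bt ranged from 252 to 1220 CPM over the 12 libraries.

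The S38A count in asynchronous cells was 875 and 1275 without WT asynchronous replicates 1 and 2 and 1263 and 1059 without S38A asynchronous replicates 1 and 2. The S38D count was 237 and 331 without WT asynchronous replicates 1 and 2, 543 without S38D asynchronous replicate 1, and 3079 without S38D asynchronous replicate 2. Genes called in the same direction in both mutant lines numbered 646 (344 higher, 302 lower) against 59.6 and 41.2 expected from the margins, and 21 were called in opposite directions. Both lines were set against the same 2 WT libraries, so part of this excess may come from shared controls. With groups drawn without differences, 20 simulations gave at most 1 such gene, a value that leaves out the effects and so does not size that part. The covariance of the fold changes over all genes was 0.307 (r = 0.663), against a mean of 0.0777 (r = 0.546) in the simulations. That overlap was 172 and 251 without WT asynchronous replicates 1 and 2, 367 without S38A asynchronous replicate 2, and 398 and 1725 without S38D asynchronous replicates 1 and 2.

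In mitotic cells the same question gave several of the same genes and a further group. These were the cholesterol biosynthesis genes, which were lower in both mutant lines, each set against the same WT mitotic libraries. Ptprcap was at 0.449 ± 0.133 CPM in S38A, 0.181 ± 0.256 CPM in S38D (2 reads) and 33.2 ± 1.66 CPM in WT (SD, n = 2). The interferon-induced surface protein gene Ly6a fell in S38A, from 143 ± 9.47 CPM in WT to 10.6 ± 1.16 CPM. Trib3 fell in S38D, from 216 ± 19.1 to 25.5 ± 1.49 CPM. The edgeR test called 1785 genes in S38A (871 higher, 914 lower, 494 at least 2-fold) and 478 in S38D (121 higher, 357 lower, 191 at least 2-fold). Under spike-in scaling the S38D counts were 39 higher and 290 lower.

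Of 25 cholesterol biosynthesis genes in mitotic cells, 18 fell and 1 rose in S38A (21 and 1 adjusted over the list alone; median -0.91, camera adjusted p = 6.24e-18), with Msmo1 at -1.06 (SE 0.102) and Cyp51 at -1.01 (SE 0.115), enzymes of the later steps. In S38D 17 fell and none rose (19 and 1 adjusted over the list alone; median -0.80, camera adjusted p = 2.07e-27), with Fdft1, which makes squalene, at -1.54 (SE 0.146), Mvk at -1.32 (SE 0.14) and Hmgcs1 at -1.04 (SE 0.104). ATF4 targets fell in 22 of 39 cases in S38A (23 adjusted over the list alone; median -0.53, camera adjusted p = 6.24e-13) and in 24 in S38D (32 adjusted over the list alone; median -0.76, camera adjusted p = 4.49e-49), and none rose. Trib3 changed by -1.55 in S38A (SE 0.129) and -3.08 in S38D (SE 0.141), and Atf5 by -1.27 (SE 0.122) and -1.65 (SE 0.123). In S38A, 28 of 65 G1/S genes rose and 2 fell (31 and 3 adjusted over the list alone; median 0.45, camera adjusted p = 8.51e-09). There 12 of 24 germinal centre genes rose and 2 fell (14 and 2 adjusted over the list alone; median 0.60, camera adjusted p = 1.43e-06), with Bcl6, the master regulator of germinal centre B cells, at 1.18 (SE 0.126). In S38D 8 of 37 B cell identity genes rose and 2 fell (12 and 3 adjusted over the list alone; median 0.25, camera adjusted p = 0.0006; adjusted p = 0.162 with an estimated correlation), with Cd72 at 1.66 (SE 0.135) and Tnfrsf13c, the BAFF receptor gene, at 0.74 (SE 0.127).

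In mitotic S38A cells Ptprcap changed by -6.14 (SE 0.413), Car2 by -5.11 (SE 0.532), Wnt10a by -4.91 (SE 0.281) and Kcnab2 by -4.54 (SE 0.241). Map1a changed by -3.87 (SE 0.271), Ly6a by -3.75 (SE 0.176), Clec4d by -3.27 (SE 0.268) and Lat2 by -1.95 (SE 0.166). Ackr4 rose by 2.94 (SE 0.205), Nacc2 by 2.41 (SE 0.195) and Slc41a2 by 2.03 (SE 0.136). Pecam1, an adhesion molecule gene, rose by 1.94 (SE 0.171), Shisa8 by 1.87 (SE 0.156) and the splicing factor gene Cdc5l by 1.85 (SE 0.308). In mitotic S38D cells Ptprcap changed by -7.27 (SE 0.477, counting interval -10.5 to -5.58), Map1a by -4.17 (SE 0.282), Lat2 by -3.54 (SE 0.189), Clec4d by -3.34 (SE 0.272) and Crip1 (chromosome 12, 113146316 to 113153879) by -2.52 (SE 0.197). H1f0 rose by 3.11 (SE 0.287), Nacc2 by 1.46 (SE 0.203), Tmem121 by 1.42 (SE 0.186), Plxnb2 by 1.32 (SE 0.159) and the RNA-binding protein gene Mex3a by 1.34 (SE 0.28). Mex3a had an adjusted p = 0.00934, which became 0.0917 and 0.0623 without WT mitotic replicates 1 and 2 and 0.133 without S38D mitotic replicate 1. Rpl12 differed by -0.64 in S38A (SE 0.158, adjusted p = 0.0102; 47.3 ± 5.72 against 73.9 ± 0.634 CPM), a call lost without WT mitotic replicate 1 (0.0514) or S38A mitotic replicate 2 (0.133). In S38D it differed by -0.42 (SE 0.157, adjusted p = 0.153; 0.0499 without S38D asynchronous replicate 2), at 55.1 ± 10.0 CPM.

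**Figure D3:**
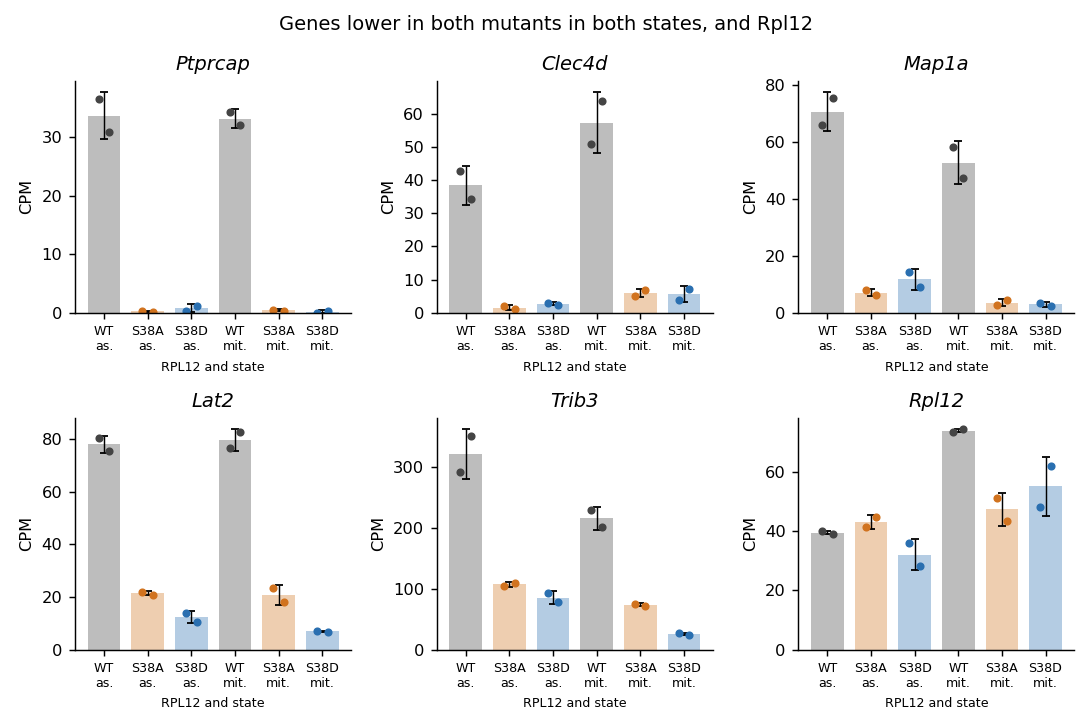
CPM of Rpl12 and the 5 genes named for calls in all 4 comparisons of a mutant line with WT, in asynchronous (as.) and mitotic (mit.) cells, with bars for the mean of 2 libraries, whiskers for the SD and dots for libraries. Ptprcap was at 33.7 CPM in WT asynchronous and 0.244 CPM in S38A asynchronous libraries.

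The S38A count in mitotic cells was 912 without WT mitotic replicate 1 and 917 and 829 without S38A mitotic replicates 1 and 2. The S38D count was 1070 and 1081 without S38D asynchronous replicates 1 and 2, 198 without WT mitotic replicate 1, and 183 and 177 without S38D mitotic replicates 1 and 2. Both mutant lines shared 221 genes called in the same direction in mitotic cells (45 higher, 176 lower; 10.1 and 31.1 expected), with 21 opposite. Both lines were again set against the same 2 WT libraries, which may add to this excess. The simulations gave at most 1 such gene here too, and a mean covariance of 0.0736 (r = 0.508) against 0.158 (r = 0.439) observed, an r below that of the simulations. That overlap was 459 and 455 without S38D asynchronous replicates 1 and 2, 101 without WT mitotic replicate 1, 138 without S38A mitotic replicate 2, and 106 without either S38D mitotic replicate. Across states, 868 genes were called in the same direction in S38A (480 higher, 388 lower; 102 and 87.2 expected) and 205 in S38D (55 higher, 150 lower; 5.89 and 14.7 expected), with 13 and 4 opposite. The S38A value was 496 without WT asynchronous replicate 1, 567 and 547 without S38A asynchronous replicates 1 and 2, and 539 and 540 without S38A mitotic replicates 1 and 2. The S38D value was 124 without either WT asynchronous replicate, 131 without WT mitotic replicate 1, and 116 and 114 without S38D mitotic replicates 1 and 2. In all 4 comparisons of a mutant line with WT, 106 genes were called in the same direction, 22 higher and 84 lower, among them Ptprcap, Map1a, Lat2, Clec4d and Trib3.

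Genes on chromosome 12, a group chosen after the values were seen, were higher in S38A than in WT relative to the median of all genes, by 0.48 in asynchronous and 0.61 in mitotic cells. Of 383 tested genes there, 144 were called higher and 17 lower in asynchronous cells (median 0.46) and 152 higher and 7 lower in mitotic cells (median 0.63). In S38D the medians were -0.06 and 0.07. Outside chromosome 12, 2062 and 1626 genes were called in S38A. Crip1 and Tmem121 lie on this chromosome and went opposite ways. In asynchronous cells Crip1 was at 118 ± 4.57 CPM in S38A and 30 ± 2.06 CPM in WT (SD, n = 2). Tmem121 was at 3.54 ± 0.124 CPM in S38A and 12.4 ± 0.232 CPM in WT. Ackr4 lies in a window of chromosome 9 (96196275 to 105687657) with medians of 0.35 and 0.62 in S38A.

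**Figure D4:**
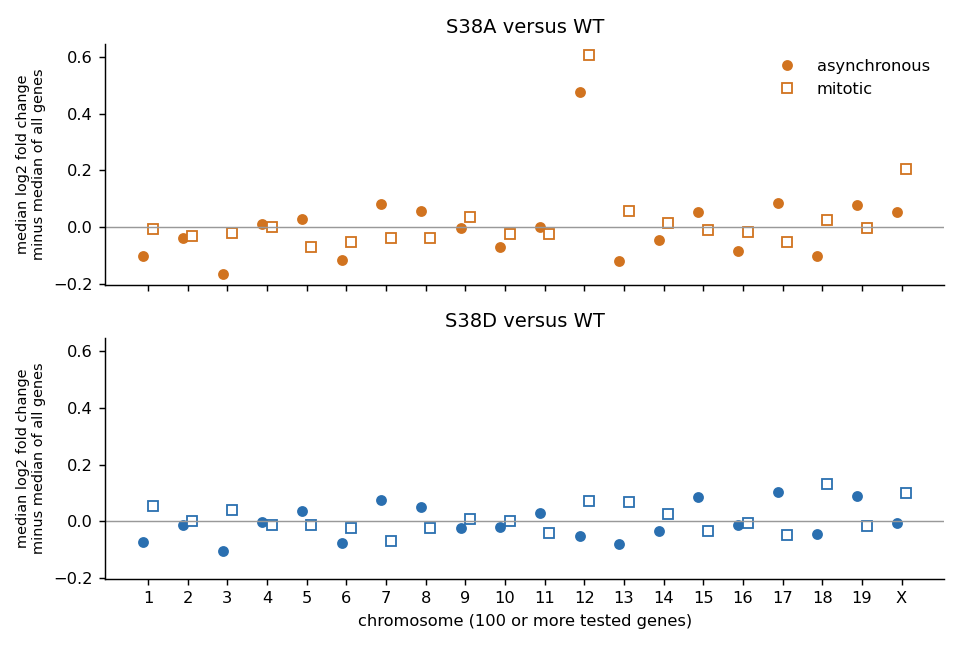
Median log2 fold change of the genes of each chromosome, less the median of all genes, for S38A and S38D against WT in asynchronous (filled circles) and mitotic (open squares) cells. Chromosome 12 departed by 0.48 and 0.61 in S38A and by -0.05 and 0.07 in S38D.

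S38D was then set against S38A, to ask how the lines with the 2 replacements of the same residue differed. Wnt10a was at 36.4 ± 3.23 CPM in S38D and 0.653 ± 0.191 CPM in S38A (SD, n = 2), and Kcnab2 at 79.3 ± 15.4 and 3.56 ± 0.576 CPM, in asynchronous cells. Crip1, a LIM domain protein gene, was lower in S38D, at 8.97 ± 1.94 against 118 ± 4.57 CPM. In asynchronous cells 4 of 18 replication-dependent histone genes were called higher in S38D and none lower, a list call with an adjusted p = 0.0941 with an estimated correlation. The edgeR test called 756 genes in asynchronous cells (348 higher, 408 lower in S38D) and 1851 in mitotic cells (787 higher, 1064 lower). Under spike-in scaling these were 258 higher and 144 lower, and 394 higher and 819 lower. Of the 383 tested genes of chromosome 12, 108 were called lower and 7 higher in asynchronous cells, and 145 and 10 in mitotic cells. The share called was 30% there against 6.35% elsewhere in asynchronous cells, and 40.5% against 16.8% in mitotic cells. Since this chromosome was higher in S38A than in WT, these calls cannot be assigned to the residue. Nor can the calls elsewhere, since how each line was derived, and whether it is 1 clone, is not given.

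In asynchronous cells Wnt10a was higher in S38D by 5.74 (SE 0.268, adjusted p = 1.26e-09), Kcnab2 by 4.48 (SE 0.23), Car2 by 4.25 (SE 0.516; adjusted p = 0.0827 with only the groups compared) and Tmem121 by 3.84 (SE 0.211). Crip1 differed by -3.71 (SE 0.171), the fatty acid elongase gene Elovl7 by -2.40 (SE 0.299) and Arhgap4 by -2.22 (SE 0.2). In mitotic cells Car2 differed by 5.78 (SE 0.523), Wnt10a by 4.95 (SE 0.279), Kcnab2 by 4.32 (SE 0.241) and Tmem121 by 3.49 (SE 0.222). Crip1 differed by -3.92 (SE 0.19), Ackr4 by -3.47 (SE 0.215), Slc41a2 by -2.78 (SE 0.142) and Arhgap4 by -2.65 (SE 0.227). Histone genes were called higher in 4 of 18 cases in asynchronous cells (11 adjusted over the list alone; median 0.91, camera adjusted p = 6.42e-08; adjusted p = 0.0941 with an estimated correlation), with Hist1h1c at 1.34 (SE 0.11). In mitotic cells 15 of 66 G2/M genes were lower and none higher (17 and 0 adjusted over the list alone; median -0.29, camera adjusted p = 0.000243), with the anaphase activator Cdc20 at -0.78 (SE 0.116). Of 65 G1/S genes 20 were lower and 2 higher there (24 and 2 adjusted over the list alone; median -0.25, camera adjusted p = 0.000226), with Cdc6 at -1.15 (SE 0.119). Rpl12 differed by -0.42 (SE 0.162, adjusted p = 0.137; 0.027 without S38D asynchronous replicate 1, 0.0132 without WT mitotic replicate 1 as well, 0.00866 with the within-group axis as a covariate) in asynchronous and 0.22 (SE 0.159, adjusted p = 0.382) in mitotic cells. The asynchronous count was 225 and 250 without S38A asynchronous replicates 1 and 2 and 1350 and 1392 without S38D asynchronous replicates 1 and 2. The mitotic count was 841 and 838 without S38A mitotic replicates 1 and 2 and 954 and 702 without S38D mitotic replicates 1 and 2.

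The last comparisons tested whether the mitotic change itself differed between lines. Cholesterol biosynthesis genes changed less upward or more downward in both mutant lines than in WT. Both tests subtract the same WT libraries, so a departure of those libraries would move both, and the lines do not support each other independently. In S38A against WT, 13 of 25 were called lower and none higher (17 and 1 adjusted over the list alone; median -0.73, camera adjusted p = 8.46e-20), with Fdft1 at -1.57 (SE 0.202, adjusted p = 0.00207), Msmo1 at -1.25 (SE 0.143) and Cyp51 at -1.20 (SE 0.162). In S38D against WT, 9 were called lower and none higher (13 and 0 adjusted over the list alone; median -0.68, camera adjusted p = 8.93e-12), with Hmgcs1 at -1.17 (SE 0.147, adjusted p = 0.00638) and Fdft1 at -1.49 (SE 0.204, adjusted p = 0.00926). Under spike-in scaling the medians were -0.27 and -0.35, with 6 lower and 1 higher in S38A and 0 called in S38D by edgeR. The S38A call of Fdft1 had an adjusted p = 0.0506 and that of Cyp51 an adjusted p = 0.0537 without WT asynchronous replicate 1. Both S38D calls were lost under spike-in scaling (adjusted p = 0.137 for Hmgcs1 and 0.0844 for Fdft1) and with only the groups compared (0.0697 for each). They were also lost without WT asynchronous replicate 1 (0.128 and 0.148) or 2 (0.0696 for each), WT mitotic replicate 1 (0.0518 and 0.0534), and S38D mitotic replicate 1 (0.0898 and 0.107) or 2 (0.121 for each). Fdft1 alone lost its S38D call with limma-voom (0.0634) and with robust estimation off (0.0513). The edgeR test called 104 genes for S38A against WT (52 higher, 52 lower), 42 for S38D against WT (15 and 27) and 4 for S38D against S38A (1 and 3). Scaled to the spike-ins, these were 482 higher and 9 lower, then 0 genes in each of the other tests, with 1615 and 787 genes at an unadjusted p under 0.05. DESeq2 called 170, 126 and 13 genes and limma-voom 25, 1 and 1. With only the groups compared edgeR called 939, 0 and 2, with 1530 genes at an unadjusted p under 0.05 beside the 0. With single libraries left out these counts ranged from 4 (without WT asynchronous replicate 1) to 1218 (without S38D asynchronous replicate 1), from 0 (without WT asynchronous replicate 1, with 1206 genes at an unadjusted p under 0.05 in edgeR) to 2666 (without S38D asynchronous replicate 2), and from 0 (without S38A asynchronous replicate 1, with 607 genes at an unadjusted p under 0.05) to 354 (without S38D asynchronous replicate 2). Rpl12 differed by -0.76 for S38A against WT (SE 0.227, adjusted p = 0.106), -0.12 for S38D against WT (SE 0.228, adjusted p = 0.79) and 0.64 for S38D against S38A (SE 0.227, adjusted p = 0.448). The first of these had an adjusted p = 0.0152 and 0.0177 without S38D asynchronous replicates 1 and 2, 0.0241 without a filter and 0.0163 with only the groups compared. Without both doubted libraries, S38D asynchronous replicate 1 and WT mitotic replicate 1, the first had an adjusted p = 0.0155 and the last 0.0444. The last had an adjusted p = 0.0145 with the within-group axis as a covariate.

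**Figure D5:**
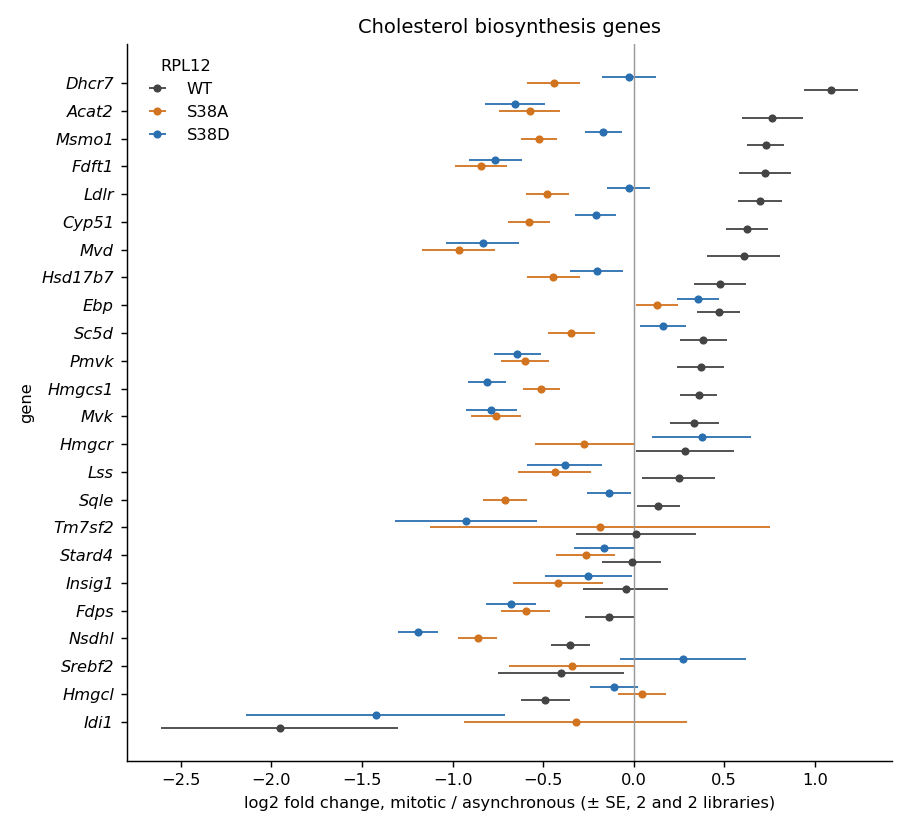
Log2 fold change (± SE) of 24 of the 25 cholesterol biosynthesis genes, mitotic against asynchronous, in WT, S38A and S38D; over the 25 genes the medians were 0.36, -0.44 and -0.21. Under spike-in scaling the WT median turned to -0.09, and those of S38A and S38D were -0.43 and -0.32.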

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

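In this part the test of GC content and the fits with the axis as a covariate or without both doubted libraries were chosen after the results were seen. The results below were singled out because the mitotic change differed between lines by a direct test of the difference. The edgeR test called 104 genes for S38A against WT, 42 for S38D against WT and 4 for S38D against S38A.

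Cholesterol biosynthesis genes had a median difference of -0.73 for S38A against WT and -0.68 for S38D against WT, calls that held with an estimated correlation (adjusted p = 0.00337 and 0.0146), and 0.13 for S38D against S38A (adjusted p = 0.299 with an estimated correlation). With spike-in scaling the first pair of medians was -0.27 and -0.35. It was -0.81 and -0.58 with the within-group axis as a covariate, and -0.86 and -0.58 with both doubted libraries left out. Both medians of the pair rest on the same WT libraries, so they are not independent of each other. For S38D against WT, tubulin genes stood at -0.67, immediate early genes at 0.18, ATF4 targets at -0.35, ER unfolded protein response genes at 0.31 and OXPHOS genes at -0.25, with adjusted p = 0.356, 0.593, 0.593, 0.419 and 0.715 with an estimated correlation. Under spike-in scaling the ATF4 median turned to 0.00388 and the OXPHOS median to 0.09. For S38D against S38A, G1/S genes stood at -0.26, tubulin genes at -0.33, ATF4 targets at -0.25, ER unfolded protein response genes at 0.21 and germinal centre genes at -0.28, with adjusted p = 0.0704, 0.404, 0.404, 0.398 and 0.146 with an estimated correlation.

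Single genes for S38A against WT were Sap30, a subunit of a histone deacetylase complex, at 2.45, Birc2, an inhibitor of apoptosis, at 2.43, Marcks at 1.97, the ribosome maturation factor Sbds at 1.79, the ETS factor Etv4 at -1.97, and the cholesterol enzymes Mvd at -1.58, Fdft1 at -1.57 and Dhcr7 at -1.53. For S38D against WT they were Sap30 at 2.11, Tmem128 at 1.37, Marcks at 1.34, Cebpb at 1.26, Ackr4 at -1.66, Fdft1 at -1.49, Nrep at -1.48 and Eif5b at -1.44. For S38D against S38A they were the small nucleolar RNA host gene Zfas1 at 1.23, Ackr4 at -1.94, the topoisomerase gene Top1 at -1.24 and Trib3 at -1.20. Of these only Marcks for S38A kept its call without each library in turn; Fdft1 and Dhcr7 for S38A lost it only without WT asynchronous replicate 1 (adjusted p = 0.0506 and 0.0537). With only the groups compared, the 8 genes for S38D against WT had adjusted p from 0.0697 to 0.193. Top1 and Trib3 for S38D against S38A had 0.299 and 0.221. The same 8 genes also lost their calls with limma-voom (adjusted p from 0.0634 to 0.119) and with robust estimation off (0.0513 to 0.0948). Both settings ended the calls of Trib3, Top1 and Ackr4 for S38D against S38A, and of Etv4 and Sbds for S38A against WT. Limma-voom also ended that of Sap30 for S38A (0.0554).

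Among the libraries of these tests, S38D asynchronous replicate 1 and WT mitotic replicate 1 depart from their replicates along 1 axis of genes. A wrong label was argued against, since 0 of 12 libraries were assigned to another line or state from genes called elsewhere. The log2 ratios of replicate 1 to 2 in these groups correlated across 29 spike-in species (Pearson r = 0.601, two-sided permutation p = 0.00057; Spearman rho = 0.597, permutation p = 0.00078; r = 0.485 without the 2 farthest species), which are not independent replicates, and in S38D asynchronous genes with the lowest 3′ GC content (15.3% to 35.7%) had a median ratio that differed by -0.448 from that of genes with the highest (51% to 71%), against -0.133 in WT mitotic and -0.0953 to 0.0939 in the other groups. GC content goes with the departure clearly in S38D asynchronous alone. Across the spike-ins the SD of the log2 ratio was 0.207 in S38D asynchronous. In WT mitotic it was 0.156, the same as in S38D mitotic and below WT asynchronous (0.164), so this spread does not set WT mitotic apart. A technical departure in library preparation or sequencing could give the spike-in correlation, since spike-ins hold no cell biology. A biological difference between the cultures stays open beside it. Fits without either replicate leave 1 library to stand for its group. Without S38D asynchronous replicate 2, that library is the departing replicate 1. Counts of called genes from such fits therefore do not tell the explanations apart.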

How the results depend on the processing

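The covariate for the within-group axis, the GC offset and the omission of both doubted libraries were chosen after seeing the data. Among 125 named results, none that was called in the main or the alternative fit changed sign. No list called by camera in the main fit was called in the opposite direction. Sign changes without a call were not counted as reversals. Camera sets a list against the other genes, so a shift common to all genes does not test its direction. Spike-in scaling turned the sign of several list medians, given beside those lists. Except where a construction is named the cause was not tested. In simulated data, where genes varied independently, 51% of genes planted at 2-fold were recovered for S38A against WT in mitotic cells. Of 125 named results, limma-voom kept 111 on their side of the threshold, spike-in scaling 112, the 10 CPM filter 117, the GC offset 118 and the axis covariate 123. The omission of both doubted libraries kept 117, and single omissions kept 106 to 123. With only the groups compared 89 of 104 kept their side. Of 128 list calls, an estimated correlation kept 47, fry 119, spike-in scaling 116, no filter 118, the 10 CPM filter 119 and single omissions 116 to 127.

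Counts that moved by more than 1.5-fold were as follows. With DESeq2 they were 987 (mitotic change in S38A), 1789 (mitotic change in S38D), 1458 and 1091 (S38A against WT, asynchronous and mitotic), 623 and 295 (S38D against WT), 451 and 1065 (S38D against S38A), and 170, 126 and 13 for the differences in mitotic change (S38A against WT, S38D against WT, S38D against S38A). The overlaps became 428 and 140 between mutant lines (asynchronous, mitotic) and 561 across states in S38A. With limma-voom the differences in mitotic change were 25, 1 and 1. With spike-in scaling counts were 932 (mitotic change in S38A), 1133 (S38A against WT, mitotic), 402 and 1213 (S38D against S38A), 491, 0 and 0 for the differences, and 1055 for the asynchronous overlap of mutant lines. Beside these counts of 0, 1615 and 787 genes had an unadjusted p under 0.05 in edgeR. Without a filter they were 1585 and 718 (S38D against WT), 616, 726 and 23 for the differences, and 1071 for the asynchronous overlap. The 10 CPM filter gave 27 and 1 for the S38D differences, and robust estimation off gave 26, 1 and 1. The replicate block, although replicate numbers do not pair the samples consistently, gave 95 and the GC offset 26 for the S38D difference from WT.

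With only the groups compared in the fit, which leaves fewer samples for the spread, counts were 2555 (mitotic change in S38A), 1172 (in S38D), 3913 and 89 (S38A and S38D against WT, asynchronous), 114 and 3120 (S38D against S38A), and 939, 0 and 2 for the differences. Beside that count of 0, 1530 genes had an unadjusted p under 0.05 in edgeR. The overlaps were 77 between mutant lines in asynchronous cells and 67 across states in S38D. With the axis as a covariate they were 3180 (mitotic change in S38A), 3182 and 1245 (S38A and S38D against WT, mitotic), 2383 and 3423 (S38D against S38A), and 560, 115 and 420 for the differences, with overlaps of 563 (mutant lines, mitotic), 1530 and 441 (across states in S38A and S38D). With both doubted libraries left out they were 2913 (mitotic change in S38A), 3871 (S38A against WT, asynchronous), 1926 and 3183 (S38D against S38A), and 803 and 154 for the differences of S38A from WT and S38D from S38A.

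With 1 library left out, counts ranged from 3801 to 4946 for the mean mitotic change, 1121 (without WT asynchronous replicate 1) to 3731 in WT, 630 (without S38A asynchronous replicate 1) to 2446 (without S38D asynchronous replicate 1) in S38A, and 1462 (without S38D mitotic replicate 2) to 3730 in S38D. In asynchronous cells they ranged from 875 (without WT asynchronous replicate 1) to 3331 for S38A against WT, 237 (without the same library) to 3079 (without S38D asynchronous replicate 2) for S38D against WT, and 225 (without S38A asynchronous replicate 1) to 1392 (without S38D asynchronous replicate 2) for S38D against S38A. In mitotic cells they ranged from 829 (without S38A mitotic replicate 2) to 2591, 177 (without S38D mitotic replicate 2) to 1081 (without S38D asynchronous replicate 2), and 702 (without S38D mitotic replicate 2) to 2715. The differences ranged from 4 (without WT asynchronous replicate 1) to 1218 (without S38D asynchronous replicate 1) for S38A against WT, 0 (without WT asynchronous replicate 1, among others) to 2666 (without S38D asynchronous replicate 2) for S38D against WT, and 0 (without S38A asynchronous replicate 1, among others) to 354 (without S38D asynchronous replicate 2) for S38D against S38A. Overlaps ranged from 172 to 1725 and from 101 to 459 between mutant lines (asynchronous, mitotic), and from 496 to 1248 and 114 to 296 across states (S38A, S38D). Beside the counts of 0 for S38D against WT and S38D against S38A, 1206 and 607 genes had an unadjusted p under 0.05 without WT asynchronous replicate 1 and S38A asynchronous replicate 1. List calls ranged from 121 to 134.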

Other observations

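In this part the class of small RNAs, the tests of the chromosomes, and the test of the axis on small RNAs were chosen after the results were seen. Small nuclear and nucleolar RNAs, which act in splicing and in the processing and modification of other RNAs, were higher in mitotic libraries. Of 38 measured, 32 rose and none fell in the mean mitotic comparison (edgeR, median 2.02), with Snora47 at 5.12 (SE 0.282, adjusted p = 1.47e-09) and Snora21 at 4.09 (SE 0.396, adjusted p = 7.13e-07). Nuclear-retained long noncoding RNAs rose in 6 of 11 cases and fell in 1 (7 and 1 adjusted over the list alone; median 0.49, camera adjusted p = 0.0085; adjusted p = 0.0781 with an estimated correlation), with Malat1 at 1.34 (SE 0.137) and Pvt1 at 1.16 (SE 0.148). In the WT line this list's median of 0.37 turned to -0.06 under spike-in scaling.

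Several lists moved in 1 comparison or a few. In asynchronous S38A cells 12 of 49 translation factor genes rose and 2 fell (16 and 2 adjusted over the list alone; camera adjusted p = 0.00453; adjusted p = 0.28 with an estimated correlation), and 10 of 24 detained-intron genes rose and none fell (12 and 0 adjusted over the list alone; camera adjusted p = 0.00453; adjusted p = 0.28 with an estimated correlation). Their medians of 0.18 and 0.36 turned to -0.29 and -0.09 under spike-in scaling. In asynchronous S38D cells 7 of 76 OXPHOS genes rose and none fell (12 and 0 adjusted over the list alone; camera adjusted p = 0.000118; adjusted p = 0.362 with an estimated correlation), with a median of 0.23 that turned to -0.16 under that scaling. There 7 of 32 p53 targets fell and none rose (8 and 0 adjusted over the list alone; median -0.25, camera adjusted p = 0.00341; adjusted p = 0.0687 with an estimated correlation), with the apoptosis gene Bbc3 at -1.11 (SE 0.124), and 2 of 6 immunoglobulin constant region genes fell (the same adjusted over the list alone; median -0.58, camera adjusted p = 0.0124; adjusted p = 0.0975 with an estimated correlation), with Ighg3 at -1.77 (SE 0.26). In mitotic S38D cells 3 of 30 NF-kB targets fell and none rose against WT (7 and 1 adjusted over the list alone; median -0.24, camera adjusted p = 0.00468; adjusted p = 0.0942 with an estimated correlation). Between S38D and S38A, 6 of 31 ER unfolded protein response genes were higher and 2 lower in mitotic cells (the same adjusted over the list alone; median 0.28, camera adjusted p = 0.0246; adjusted p = 0.276 with an estimated correlation), with the chaperone gene Hyou1 at 0.95 (SE 0.192; adjusted p = 0.0636 without S38D mitotic replicate 2). Among 18 interferon-stimulated genes 2 were lower and 1 higher in asynchronous cells (5 and 2 adjusted over the list alone; median -0.67, camera adjusted p = 0.0182; adjusted p = 0.164 with an estimated correlation).

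Lists of heat shock, apoptosis, proteasome, glycolysis, plasma cell and myeloid genes were called in none of the 13 comparisons. In the mean mitotic comparison they had 9 genes called higher and 8 lower of 29, 2 and 12 of 27, 3 and 5 of 35, 10 and 7 of 33, 4 and 10 of 16, and 0 and 0 of 4 measured (camera adjusted p = 0.786, 0.104, 0.791, 0.474, 0.468 and 0.8). Myeloid markers reached at most a mean of 4.5 CPM (Fcgr3), and the T and NK cell list, with too few measured members for a test, a mean of 4.06 CPM (Klrb1c).

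The higher small RNAs of mitotic libraries are 1 pattern. A displacement along the axis of replicate differences was argued against, since with the axis as a covariate the median kept at least 83% of its size in each line. RNA of the interphase nucleus may enter the cleared lysate once the nuclear envelope is gone, which the median of 0.492 for nuclear-retained long noncoding RNAs is in line with. Neat1 (0.01, adjusted p = 0.91) and Ftx (-0.46, adjusted p = 0.0334) did not rise, and detained-intron and nuclear-retained mRNAs, another nuclear class, had a median of 0.155 (9 of 24 higher, 4 lower, camera adjusted p = 0.468) that turned to -0.02 under spike-in scaling, so this explanation covers some of the RNAs at best. A change in the tailing or stability of these RNAs in mitosis was not tested, nor was whether reads of 3′ mRNA libraries follow their amount.

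The difference between the lines in both states is another pattern. The axis was tested on the genes called in the same direction in both states (868 in S38A, 205 in S38D). With the axis as a covariate they kept a median of 96.9% to 102% of their fold change in each comparison. Of them 97.5% (1046 of 1073) kept their calls, in a fit that made more calls and, in simulated data, 14 false calls against 2. These genes were chosen by their calls without the covariate, where movement along the axis counts as spread. The choice thus favours genes that the axis moves little. For these genes the values argue against the axis, and genes outside this set were not tested. Copy number of the chromosome that carries a gene was judged by where the called genes lie. Chromosome 12, the only one to depart by over 0.3 in both states of a comparison (S38A), held at most 8.91% of the genes called there. No chromosome departed by over 0.13 in S38D. A first form of this rule was a bound on the departure of any chromosome. Chromosome 12 exceeded it (0.607), and the share of called genes replaced it. Chromosome 12 has 383 tested genes, against 2223 and 1785 genes called in S38A (asynchronous, mitotic). Once it alone departed, the outcome of the new rule was settled, so the share only tells where called genes lie. For chromosome 12 alone, an additional copy in the S38A line could give the medians of 0.296 or more in each of 5 parts of its genes in both states. For genes elsewhere, a departure of at most 0.206 argued against copy number of the whole chromosomes that carry them. Effects of an additional chromosome 12 on genes elsewhere were not tested and stay open in S38A. The effect of the RPL12 change itself and other changes fixed when each line was made stay open, since how the lines were derived, and whether each is 1 clone, is not given in the sources used here.

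One hypothesis concerned tubulin. Free tubulin dimers are known to set off decay of tubulin mRNA, and nocodazole releases dimers. The median of 9 alpha- and beta-tubulin genes (-1.30) differed by -1.14 from that of 29 other microtubule genes (-0.16), with a two-sided permutation p = 1e-04 across genes, which are not independent replicates. This suggests that the decrease reached tubulin genes beyond the level of microtubule genes in general, while Tubg1, a gamma-tubulin gene, also fell (-0.57, SE 0.0738, adjusted p = 1.3e-05). Mitotic state and drug were applied together, so they were not separated.

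The split of the 12 libraries into mitotic and asynchronous was compared with other splits into 6 and 6, with line as a term. Only 1 of 100 splits, the real one, gave as many called genes (3898 in edgeR), and the highest of the others gave 0. At an unadjusted p under 0.05 the others had at most 2953 genes, against 4807 for the real split. By rank this argues against chance for that count if the 12 libraries are independent, which the labels do not settle for the replicates of a group. The other splits leave the mitotic difference in their residual spread, so the gap between 3898 and 0 does not size the effect. Of 462 possible splits only these 100 were run.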
